A study of Mus musculus with 260 samples.

How the data were processed

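CUT&RUN is an assay in which an antibody directs a nuclease to a protein or histone mark in isolated nuclei, so that the released DNA fragments map where that protein or mark lies. Per the labels' protocols, nuclei from mouse nucleus accumbens were prepared on a sucrose gradient and processed by CUT&RUN before library construction. The protocols also name purification by INTACT, a method of tagged-nucleus capture. Whether that step applied to the libraries labelled bulk, which have no cell type given, was not established here. The submitters' processing notes name Bowtie2 2.4.1, SAMtools 1.10, deepTools and MACS2 2.2.6 and the mouse genome build mm10. The roles of these tools, their parameters, the scaling of the signal tracks and the way in which replicates were combined are not given in the sources used here.

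The material analysed here was a catalogue that the authors deposited, a table with 12 columns and one line for each of 140 processed files. Its columns give a file's name, type, checksum and title, and the tissue, organism, genotype, cell type, sex, treatment, antibody and route of administration. None of its cells is a number (0 numeric cells). It holds no coverage, peak position, peak height, read count or p-value. The signal tracks and peak lists that it names were not analysed here, and sequencing depth per library is therefore unknown. No fold change, overlap of peaks, enrichment or test of a difference between groups was computed, and no gene or region is named as a result.

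Each of the 260 libraries was placed in one of 88 groups by its title with the replicate number removed. The title of every catalogue entry was then compared with the group names, using Python 3.11.15. The main comparison took the whole title exactly as written. Other settings fixed before the data were examined ignored case and surrounding blanks, or used the name of the listed file. That name was set against the short library code with the digit after its opening letters removed. A further setting, chosen after the data were seen, also folded a misspelling of cocaine and an added word "bulk". The labels of each matched entry were compared with those of the libraries in its group. The steps that fold titles and codes were tested on made-up names.

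The tests fixed at the same time covered cocaine against saline, D1 against D2 neurons, the pair of Fosb genotypes, the routes of administration and the overlap of peak sets. They required per-library values or peaks and were not run. The rule for named genes, including lists of AP-1 and BAF subunits, neuron-type markers, cocaine-linked genes and markers of other cell types, was likewise not applied.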

Results

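The study was designed to map the binding of the transcription factor ΔFOSB, the coverage of the chromatin remodeller BRG1 and 4 histone modifications in the mouse nucleus accumbens after chronic cocaine. The nucleus accumbens is a striatal region of the brain's reward circuitry. Its principal cells are medium spiny neurons, which fall largely into D1 and D2 types according to the dopamine receptor they express. ΔFOSB is a truncated, long-lived product of the Fosb gene that accumulates in this region with repeated drug exposure, and BRG1, encoded by Smarca4, is an ATPase of the BAF complex. No measurement of binding, coverage or histone modification was analysed here, so the account is limited to the design of the experiment and to the outputs named in the authors' catalogue.

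The series comprised 260 CUT&RUN libraries, 132 from cocaine-treated and 128 from saline-treated animals. Nuclei of D1 neurons gave 108 libraries, nuclei of D2 neurons gave another 108, and 44 were labelled bulk, with no cell type given. The libraries formed 88 groups, of which 84 had 3 replicates and 4 had 2. The labels did not say whether replicates came from separate animals or from pools.

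FosB antibody was used in 46 libraries and Brg1 antibody in 24. Whether the FosB antibody separates ΔFOSB from other products of the Fosb gene was not established here. The histone modifications were H3K4me1, a mark of enhancers, H3K4me3, a mark of active promoters, H3K27ac, a mark of active promoters and enhancers, and H3K27me3, the repressive mark laid down by Polycomb complexes. Each was profiled in 24 libraries. The remaining 94 libraries were made with non-specific IgG, which measures the background of the assay. Separate IgG groups accompanied the FosB, the Brg1 and the histone experiments.

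The design set cocaine against saline within each cell type and sex. The D1 and D2 libraries carried the genotype label wild-type, which names no nuclear tag although INTACT captures tagged nuclei. Each combination of cell type, treatment and sex in the title held 27 libraries in 9 groups. These were FosB, Brg1, the 4 histone marks and their IgG controls. The animals of the D1 and D2 libraries received injections over 7 days. A comparison of 3 cocaine with 3 saline libraries cannot give an exact two-sided permutation p below 0.1 for a single region.

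Another part of the design addressed the route of drug delivery in bulk nuclei from males labelled wild-type. Injected animals contributed 6 libraries per treatment, as did animals that self-administered cocaine or saline intravenously for 2 hours per day over 10 days. In each case the libraries were split between FosB antibody and IgG. The routes differed in duration as well as in mode of delivery.

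The genotype part of the design compared Fosb-flox/+ males with Sox2-Cre; Fosb-flox/flox males, whose groups were titled null. These libraries were also labelled bulk, and the animals received injections over 7 days. Sox2-Cre drives recombination in the epiblast, so that a floxed gene is removed throughout the embryo. Such animals allow FosB antibody signal to be set against tissue labelled as carrying Cre and no unfloxed Fosb allele. By their labels, the compared genotypes differ in Cre as well as in the number of floxed alleles. Each genotype had 4 libraries after saline and 6 after cocaine, split between FosB antibody and IgG. The saline arms of this comparison were the only groups with 2 replicates.

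The catalogue named 140 processed files, 88 signal tracks and 52 peak lists. It gave exactly 1 signal track for each of the 88 groups, and each title lacked a replicate number. Each group would thus give 1 value per region from its track, with no spread between replicates. How a track was made from the replicates of its group is not given. Of the 56 groups made with a specific antibody, 52 had an entry for a peak list. The other 4 were the FosB groups of the Fosb-flox/+ and the Sox2-Cre; Fosb-flox/flox males, 2 for each genotype. All 32 IgG groups had a signal track and 0 had a peak list. The checksums listed for the 140 files were all distinct, so by the catalogue no pair of files had identical content. The checksums were not compared with the files themselves.

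The catalogue and the library labels gave the same genotype, cell type, treatment, antibody and route for every matched entry. They differed in sex for 24 listed files, which covered 48 libraries. Among 108 libraries titled female, 60 carried the sex label female and 48 carried the sex label male. The 48 comprised 12 FosB libraries, 12 IgG controls of the FosB experiment, 12 Brg1 libraries and 12 IgG controls of the Brg1 experiment. All histone libraries and their controls had matching titles and sex labels. The catalogue gave female for every entry titled female, and the short codes of all 48 libraries began with F. Comparisons between sexes for FosB and Brg1 would therefore rest on the titles, codes and catalogue against the sex label.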

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

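By exact title, 120 of the 140 listed files were matched to a group, and ignoring case and blanks left the count at 120. The other 20 titles misspelt cocaine in 4 cases and added the word "bulk" in 16, and all 140 files were matched once both differences were folded, an alternative chosen after the data were seen. Matching by short code placed 128 files, and none was placed in another group than its title gave. The 12 that it left were tracks and peak lists of bulk nuclei labelled wild-type. There the injection and self-administration groups share a code once the digit after its opening letters is removed. The catalogue adds a suffix to the latter. The other settings fixed beforehand, namely the pseudocount, scaling, filter, IgG subtraction, left-out replicates and peak thresholds, were not run because they need measured values. No paired analysis was possible because the result comes from no test: the catalogue holds no value for any replicate.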
